A study of Hordeum vulgare with 12 samples.

How the data were processed

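The samples were 12 pools of 3 barley plants each, 3 pools for each of 4 growth conditions, and the labels state that each pool was a separate replicate sample. Per the labels' protocols, RNA was amplified with an Ambion kit and coupled to the dye Cy3 with a Kreatech kit, and each array held the RNA of a single pool. Whether the replicates came from separate growth chambers or sowings is not given in the sources used here, so p-values measure the spread between these pools only. The time of day at harvest and the age of the plants in days are not given either.

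The deposited scanner tables hold spot intensity on a linear scale, made with Agilent Feature Extraction 10.5.1.1, per the file headers. The processed intensity used here had been background-subtracted by that software, per the file headers, and had not been normalized between arrays. The authors also deposited a table of log2 values, for which the submitters' processing notes name R 2.7.1 and limma. Set against the scanner values, each column of the authors' log2 table equalled the log2 of the spot's median signal, without background subtraction, shifted by a constant per array (correlation of at least 0.99996, residual SD 0.0044 to 0.015). The column medians were 10.11 to 10.13, so those values were centred on the array median and are comparable between arrays only as far as that centring is. No direction is open, since each array carried a single colour.

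Values were computed as log2 of the processed signal minus the array's 75th percentile of it. Control spots and 4 to 18 spots per array that the scanner software had marked as outliers were left out, no spot was saturated, and the 5 spots of each of 50 repeated probes were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 condition, by the scanner software's own test. The 21576 tested probes entered a model of the 4 condition means in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes), with 8 residual and 2.10 prior degrees of freedom. It gave 7 contrasts, each adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All adjusted p-values in the text come from this model unless another setting is named. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

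The signal of the arrays limits their precision. The median spot was 1.27 to 1.75 times as bright as the median negative control, whose signal ran from 515 to 1273.2 and was highest on replicates 1 and 2 of short days at 15 °C. Replicate 3 of short days at 25 °C had the lowest negative controls and the most spots well above background. Without it the counts were 2696 for temperature in short days, 1227 for day length at 25 °C and 50 for the interaction. Where a named probe was not well above background on any array of 1 condition of a simple comparison, only a bound is given for that comparison. Fitted interactions of such probes rest on signals at background, as is said beside them. The bound is the mean of the brighter condition over the mean, per array, of the lowest signal among probes well above background or the probe's own signal, whichever was higher, on normalized log2 values. It holds only for the signal as the scanner software subtracted its background, and some changes with normexp lay under it. Each of the 10 bounds printed lay above the smallest change over the other settings.

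Each of 3 slides held 4 arrays, 1 of each condition, so slide and condition were not confounded, and the slide was tried as a block and each contrast was computed within each slide. Array brightness was not balanced in this way. The 75th percentile of log2 signal before scaling was 11.02 to 11.43 in short days at 15 °C and long days at 25 °C. In the other conditions it was 10.48 to 10.92. Each simple comparison thus set brighter arrays against dimmer ones, and an effect of brightness left after scaling cannot be told apart from its calls. The model was tested on simulated data with 200 changed probes among the 21576. For temperature in short days it recovered 17.9%, 52.2% and 83.3% of changes of 0.5, 1 and 2 on the log2 scale, and for the interaction 0%, 34.3% and 66.7%. In the same simulations 1 to 11 calls per contrast were false. The simulated noise was independent between arrays, and fewer probes were changed than the 3577 called for temperature in short days. These rates therefore need not hold for the data.

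The files give no gene symbol or description for any spot. Their target identifiers, 38818 in all, matched none of the 58438 genes in the reference table used, which names the assembly MorexV3, so probes are given by the array maker's identifier. Gene lists fixed before the data were examined, and the set tests planned for them, were therefore not used here. The rule for naming probes was also fixed then. Per simple comparison it takes the 2 unnamed probes with the largest called rise and the 2 with the largest called fall, and where a target has several probes the brightest stands for it. Where targets had several probes and a call, 85.7% to 93.9% had all probes of the same sign in each contrast. The rule fixed for the interaction needed gene names and could not be used. The interaction is given instead for those named probes whose interaction was called. These were picked for large simple changes and do not represent the 111 interaction calls. All of them were positive, while 53 of the 111 were negative.

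The alternatives fixed before the data were examined were normexp background correction (offset 50), quantile and array-median normalization, the authors' log2 values, no filter and a filter on all 12 arrays, array weights, an intensity trend, only the arrays compared, the replicate number as a block, the slide as a fixed or random block, and each array left out. The authors' log2 values recentred on the median of the tested probes were added after the data were seen.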

Results

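The study asked which barley transcripts respond to warm growth temperature and to day length. RNA came from whole plants without roots of the cultivar Sonja. Germinating seeds had first spent 9 weeks at 2 °C in the dark, a cold treatment called vernalization that prepares winter cereals for flowering. The plants then grew at a constant 15 °C or 25 °C, with 8 h or 16 h of light per day, and were harvested once leaf 4 could be seen. These 4 growth conditions are called here short days at 15 °C, short days at 25 °C, long days at 15 °C and long days at 25 °C. Each was represented by 3 arrays, and each array by a pool of 3 plants, so 12 Agilent barley arrays were compared. Of 43603 probes, 21576 were well above background on all 3 arrays of at least 1 condition and were tested, standing for 17773 target sequences. On 11 of the arrays 44.5% to 52.2% of spots were well above background, and on replicate 3 of short days at 25 °C the share was 69.5%.

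Temperature was the larger source of difference between the arrays. The first principal component held 30.0% of the variance and parted the 6 arrays from 15 °C plants, at -49.1 to -17.2, from the 6 from 25 °C plants, at 18.3 to 49.9. Within each temperature it also parted the day lengths, so it did not hold temperature alone. At 15 °C long days lay at -49.1 to -44.7 and short days at -25.0 to -17.2. At 25 °C long days lay at 18.3 to 26.5 and short days at 44.3 to 49.9. The next component held 16.2% and parted the 6 short-day arrays, at 15.7 to 26.1, from the 6 long-day arrays, which spread from -28.2 to 11.2 at 15 °C and from -59.5 to -15.0 at 25 °C. Arrays of the same condition correlated at 0.955 to 0.979 across probes, and arrays of different conditions at 0.925 to 0.974.

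**Figure D1:**
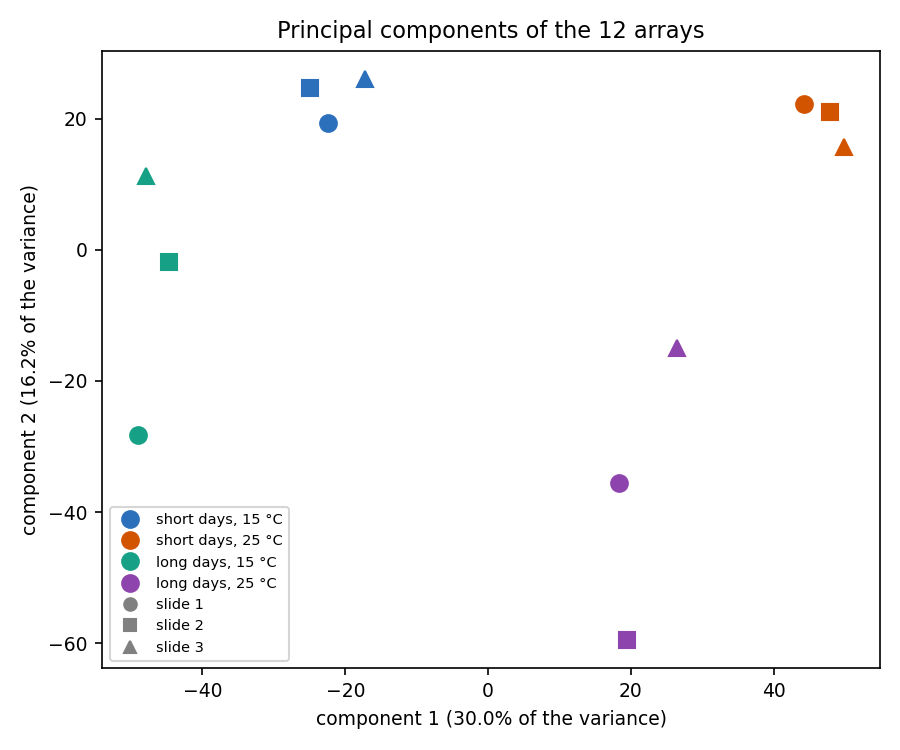
Each point is 1 of the 12 arrays, placed by its scores on the first 2 principal components of the normalized log2 values of the tested probes; colour gives the growth condition and shape the slide. The 15 °C arrays lie at or below -17.2 on the horizontal axis and the 25 °C arrays at or above 18.3.

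In short days, growth at 25 °C rather than 15 °C raised 1960 probes and lowered 1617, together 3577 of the 21576 tested (limma, adjusted p under 0.05). The median size of a called change was 0.63 on the log2 scale. A change of at least 2-fold was seen for 424 of the raised and 221 of the lowered probes, and of at least 8-fold for 37 and 9. Probe A_13_P120660 rose by 7.37 ± 0.73 on the log2 scale (SE, n = 3 arrays per condition, limma adjusted p = 0.000211), and at 15 °C it was well above background on 2 of 3 arrays, so the size rests partly on signal at background. Its rise was 5.79 with normexp and 5.19 in the authors' deposited values. Probe A_13_P212059 was not well above background on any 15 °C array and was at least 11.99-fold higher at 25 °C (adjusted p = 5.61e-05). In the opposite direction, A_13_P477163 and A_13_P267047 were not well above background on any 25 °C array of this day length. They were at least 37.7-fold (adjusted p = 6.23e-05) and at least 8.95-fold (adjusted p = 0.000168) lower than at 15 °C. These bounds hold only for the signal as the scanner software subtracted its background. With normexp the 3 probes changed by 3.52, -4.79 and -3.74 on the log2 scale, under the bounds for A_13_P212059 and A_13_P477163. In the authors' deposited values, without subtraction, they changed by 2.60, -3.75 and -2.32. The 3 arrays of each temperature did not overlap for 3555 of the 3577 called probes and for 37.4% of all tested probes, against 10% by chance. The change had the same sign on all 3 slides for 99.7% of the called probes, and with the slide as a block 3500 probes were called. Called probes were selected on these arrays. Their lack of overlap and shared sign are therefore largely fixed by the selection, here and in each comparison below. Rises made up 54.8% of the calls, but 10.6% of 2758 calls when arrays were scaled to their medians, which shifted the median change of all tested probes by -0.35 from its main value. Without replicate 2 of short days at 15 °C or replicate 1 of short days at 25 °C the count was 2166 or 2264. Normexp called 2117 of the 3577 again in the same direction.

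In long days, 2101 probes were higher and 1854 lower at 25 °C than at 15 °C, 3955 in all (limma, adjusted p under 0.05). The median size of a called change was 0.62 on the log2 scale, and 451 raised and 307 lowered probes changed at least 2-fold. A_13_P120660 rose by 6.65 ± 0.73 on the log2 scale (SE, n = 3 arrays per condition, limma adjusted p = 0.00035), with 1 of 3 arrays at 15 °C well above background, and by 4.27 with normexp and 4.44 in the authors' deposited values. A_13_P108750 was not well above background at 15 °C and was at least 20.1-fold higher at 25 °C (adjusted p = 5.62e-05). A_13_P477163 and A_13_P267047 were again not well above background at 25 °C, and lay at least 27.1-fold (adjusted p = 7.86e-05) and at least 6.63-fold (adjusted p = 0.000329) below their 15 °C levels. In the authors' deposited values these 3 probes changed by 2.86, -3.22 and -1.95 on the log2 scale, and with normexp by 2.52, -3.89 and -3.15. For 3949 of the called probes the 3 arrays of each temperature did not overlap, a state that held for 39.6% of all tested probes. The sign was the same on all 3 slides for 99.9% of the called probes, again selected on these arrays, and a slide block gave 3809 calls. Rises were 53.1% of the calls here, 39.0% of 5898 with normexp background correction and 76.0% of 3894 in the authors' deposited values. Normexp called 2384 of the 3955 again in the same direction and 7 in the opposite one. Without replicate 2 or replicate 3 of long days at 15 °C the count was 2473 or 2239. It was 909 with arrays scaled to their medians, 1830 when all probes were tested and 6441 with array weights.

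The log2 changes with temperature in the 2 day lengths, which rest on separate arrays, were alike in direction for most called probes. Higher levels at 25 °C in both day lengths were called for 1158 probes, where independent lists would share 191, and lower levels in both for 758, where they would share 139. Opposite calls were made for 37 probes, 29 of them higher in short days and lower in long days. Across the 21576 probes the log2 changes correlated at r = 0.547 (Spearman rho 0.506), and at 0.308, 0.285 and 0.375 within slides 1, 2 and 3. Probes are not independent replicates, so no p is given for these correlations. A further 1624 probes were called in short days and not in long days, and 2002 in long days and not in short days. The difference between the 2 temperature responses was itself called for 28 of the former and 44 of the latter. Averaged over the day lengths, 3421 probes were higher and 3128 lower at 25 °C, or 6549 in all. Rises were 52.2% of these calls, 22.7% of 4238 after scaling to array medians, a shift of the median change by -0.18, and 63.1% of 5712 in the authors' deposited values.

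**Figure D2:**
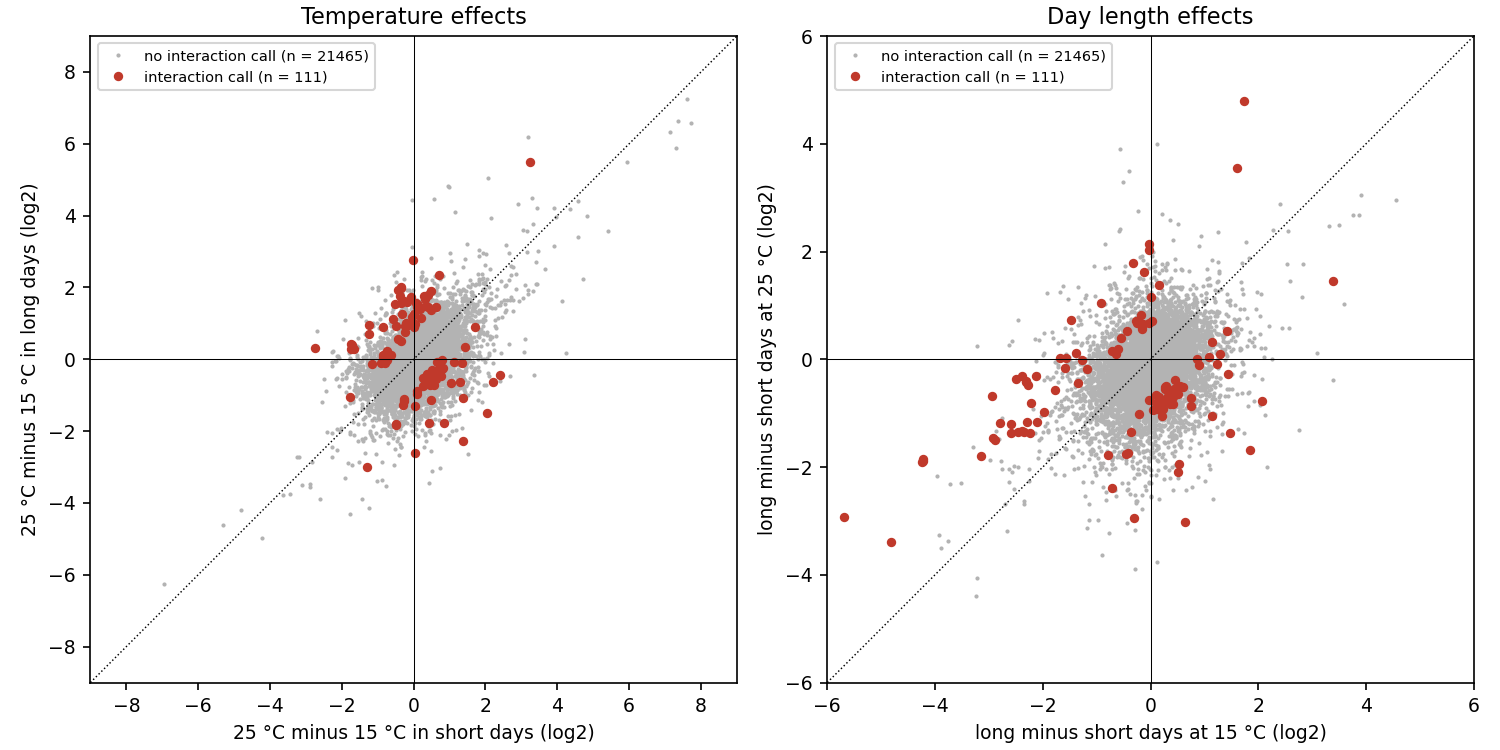
Each point is 1 of the 21576 tested probes. The left panel sets the temperature change in long days against that in short days, and the right panel the day length change at 25 °C against that at 15 °C, all as log2 differences of group means with n = 3 arrays per condition. The dotted line marks equal changes, and the 111 probes with a called interaction are in red.

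At 15 °C, long days raised 336 probes and lowered 491 relative to short days, 827 in all (limma, adjusted p under 0.05). Called changes had a median size of 0.83 on the log2 scale, and 127 raised and 201 lowered probes changed at least 2-fold. Probe A_13_P009426 rose by 3.88 ± 0.44 on the log2 scale (SE, n = 3 arrays per condition, limma adjusted p = 0.000622). A_13_P136610 was not well above background in short days at 15 °C and was at least 3.89-fold higher in long days (adjusted p = 0.000301). A_13_P000501 was not well above background in long days, where it was at least 6.55-fold lower (adjusted p = 6.64e-08). In the authors' deposited values A_13_P136610 and A_13_P000501 changed by 1.35 and -1.88 on the log2 scale, and with normexp by 1.80 and -1.52. A_13_P138385 fell by 4.23 ± 0.15 on the log2 scale (SE, limma adjusted p = 1.8e-07), and all 3 probes for its target fell, with changes of -4.23 to -4.22. The day lengths did not overlap for any of the 827 called probes, and for 24.7% of all tested probes. All 827, selected on these arrays, had the same sign on the 3 slides, and a slide block gave 710 calls. Rises were 40.6% of the calls, 65.4% of 1847 with normexp background correction, 77.9% of 1315 in the authors' deposited values, a shift of the median change by 0.10, and 54.0% of 1125 after those were recentred on the tested probes. The count was 521 without replicate 2 of short days at 15 °C, and 538, 524 and 479 without replicates 1, 2 and 3 of long days at 15 °C.

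At 25 °C, long days raised 651 probes and lowered 935 relative to short days, 1586 in all (limma, adjusted p under 0.05). Changes of at least 2-fold were fewer among the raised probes, 96, than among the lowered, 302, and the median size of a called change was 0.71 on the log2 scale. Probe A_13_P181329 was not well above background in short days at 25 °C and was at least 9.84-fold higher in long days (adjusted p = 8.43e-07), and both probes for its target were called. A_13_P000191 rose by 3.91 ± 0.99 on the log2 scale (SE, n = 3 arrays per condition, limma adjusted p = 0.0413), with changes of 2.56, 1.77 and 7.39 on the 3 slides. It was well above background on 1 of 3 short-day arrays at 25 °C, and its call was lost in 16 of 24 other settings (changes of 1.62 to 4.89, adjusted p up to 0.167). A_13_P531964 fell by 3.90 ± 0.71 (SE, limma adjusted p = 0.0104) and was well above background on 1 of 3 long-day arrays at 25 °C. Its changes on the 3 slides were -5.21, -4.52 and -1.96, its smallest change over the settings was -1.72, and its call was lost in 1 of 24 (adjusted p up to 0.0735). A_13_P439331 was not well above background on those arrays and was at least 3.81-fold lower there (adjusted p = 0.0225), a call lost in 9 of 24 other settings (adjusted p up to 0.0775). In the authors' deposited values A_13_P181329 and A_13_P439331 changed by 2.01 and -1.88 on the log2 scale, and with normexp by 2.42 and -3.79. The day lengths did not overlap for 1585 of the called probes and for 27.8% of all tested probes. Every called probe, selected on these arrays, had the same sign on the 3 slides, and a slide block gave 1395 calls. Rises were 41.0% of the calls, 55.5% of 1635 with quantile normalization, 91.8% of 2150 with arrays scaled to their medians, a shift of the median change by 0.42, and 92.3% of 6128 in the authors' deposited values, a shift of 0.22. Without replicate 1 of short days or replicate 2 of long days at 25 °C the count was 805 or 867.

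Day length responses at the 2 temperatures also shared direction. Both comparisons called 141 probes as higher in long days, where independent lists would share 10.1, and 267 as lower, where they would share 21.3, while 8 had opposite calls. These calls too shared the estimate of spread per probe, so the numbers for independent lists are again a low baseline. Across probes the log2 changes correlated at r = 0.325 (Spearman rho 0.273), and at 0.192, 0.106 and 0.123 within slides 1, 2 and 3. With normexp r was 0.167. Of the 1170 probes called at 25 °C and not at 15 °C, 47 had a called difference between the 2 day length responses, and of the 411 called at 15 °C and not at 25 °C, 25 had one. Averaged over the temperatures, 939 probes were higher and 1250 lower in long days, or 2189 in all. Rises were 42.9% of these calls, 82.2% of 1626 after scaling to array medians, a shift of the median change by 0.24, and 91.9% of 7365 in the authors' deposited values, a shift of 0.16.

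The temperature response differed between day lengths for 111 probes, standing for 99 targets (limma interaction term, adjusted p under 0.05). The change from 15 °C to 25 °C was more positive in long days for 58 of them and more negative for 53. Among the 111, 29 were higher at 25 °C in long days without a call in short days, and 15 were lower in long days without a call in short days. Another 21 were called higher at 25 °C in short days and lower in long days, and 8 the reverse. Seen as a day length response, 23 were lower in long days at both temperatures with the larger fall at 15 °C, and 32 were called lower in long days at 25 °C and not called at 15 °C. Probe A_13_P138385 belonged to the 23. It lay at 3.28 ± 0.10 and 2.94 ± 0.07 in short days at 15 °C and 25 °C, and at -0.95 ± 0.01 and 1.06 ± 0.34 in long days (normalized log2 signal, mean ± SD, n = 3). Its interaction was 2.35 ± 0.21 on the log2 scale (SE, limma adjusted p = 0.000915), and the 3 probes for its target gave 2.33 to 2.38. Where a target had several tested probes and at least 1 interaction call, its probes had the same sign for 31 of 33 targets. All 111 had the same sign on the 3 slides, but they were selected on these arrays. The slide as a fixed block gave 53 calls, 48 of them among the 111. As a random block it gave 133, with all 111 among them. The share of positive values was 52.3%, against 71.9% of 64 with quantile normalization, 89.3% of 28 with array medians, a shift of the median by 0.35, 74.3% of 109 in the authors' deposited values, a shift of 0.12, and 35.9% of 287 after recentring those. The count was 43 and 39 without replicates 1 and 2 of short days at 15 °C, 33, 47 and 50 without replicates 1, 2 and 3 of short days at 25 °C, 38, 34 and 26 without replicates 1, 2 and 3 of long days at 15 °C, and 40 without replicate 2 of long days at 25 °C.

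**Figure D3:**
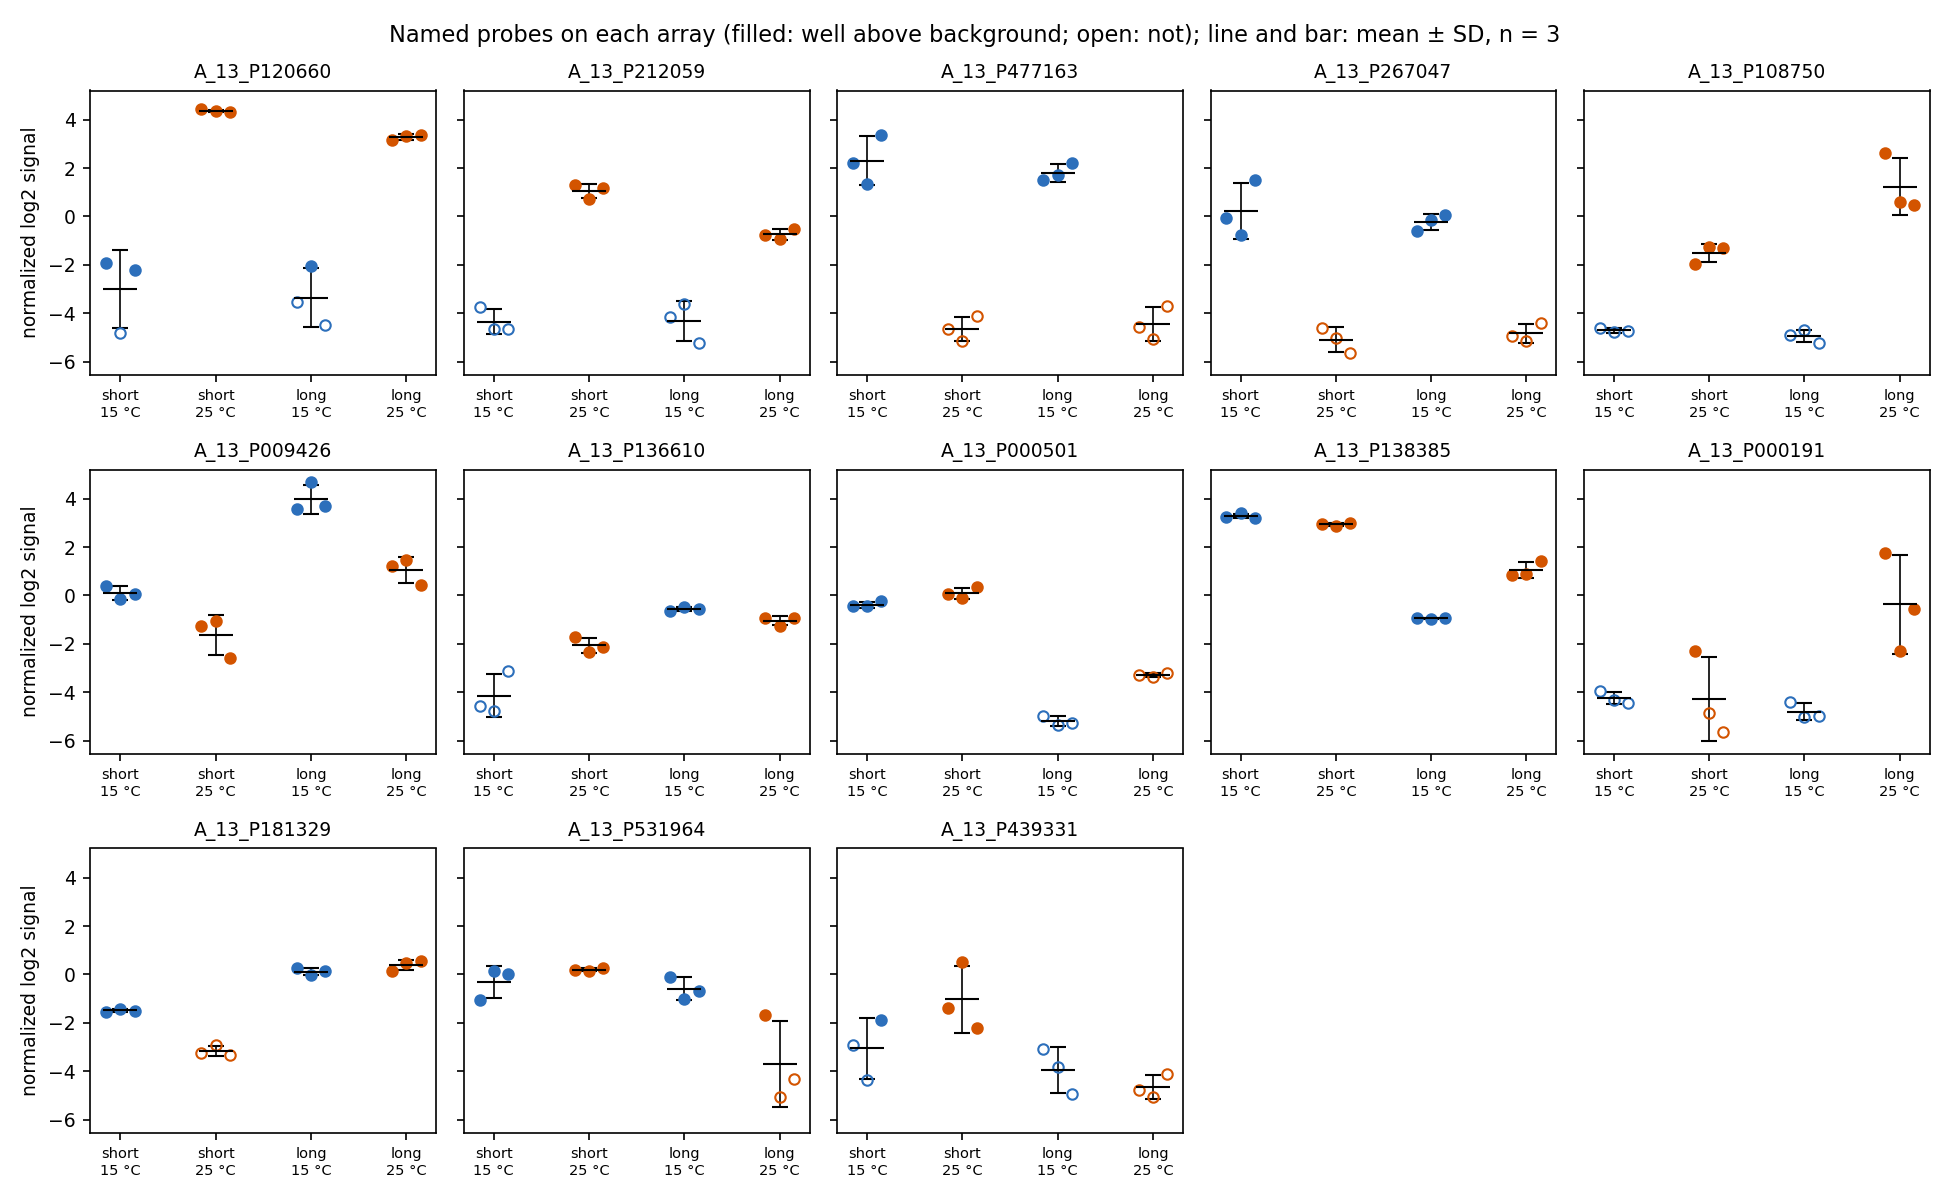
Normalized log2 signal of the 13 named probes on each of the 12 arrays, by growth condition; filled points were well above background on their array, open points were not, and lines with bars give the mean ± SD of the 3 arrays. A_13_P120660, A_13_P212059 and A_13_P108750 were higher at 25 °C in both day lengths, and A_13_P138385 lay at -0.95 in long days at 15 °C against 3.28 in short days.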

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

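The test of dim probes below was chosen after the counts it uses had been seen. A temperature response that differed between day lengths was called by the interaction term for 111 probes. Of 100 regroupings of the 12 arrays into 4 groups of 3, made without regard to slide after both averaged effects had been removed, and with the real one included, 1 gave as many calls, namely the real one, and the highest of the others gave 0. This argues against chance as the source of the count, though 1 of 100 is the smallest share the test could give. The averaged effects removed were those fitted under the real grouping, which may favour it. Probes near background in some condition were weighed as a technical explanation. Of the 111, 80.2% lay well above background on all 12 arrays, but so did 17103 of the 21576 tested probes. The share by itself therefore largely restates that of the tested probes and decides nothing. Testing only the 17103 gave 147 calls, 89 of them among the 111, so those 89 do not rest on signal at background. For the rest of the 111 this explanation was not excluded. What stays open is the size and the membership of the set. Its size ran from 20 when all probes were tested, 26 without replicate 3 of long days at 15 °C, and 53 or 133 with the slide as a fixed or random block, to 159 with an intensity trend and 441 with array weights. Normexp called 131 probes, 47 of them among the 111, and the authors' values 109, with 56 among the 111. Array brightness stays open too. Before scaling, the 75th percentile of log2 signal was 11.02 to 11.43 in short days at 15 °C and long days at 25 °C. It was 10.48 to 10.92 in the other conditions. An effect of brightness left after scaling therefore cannot be told apart from an interaction. The same holds for each simple comparison, which sets a brighter condition against a dimmer one. Growth condition itself as a biological explanation may hold but was tested only by these counts.

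Among the named probes, A_13_P138385 had an interaction of 2.35 ± 0.21 on the log2 scale (SE, limma adjusted p = 0.000915), and its call was kept in all 24 other settings, with values of at least 1.78 and adjusted p up to 0.00946. A_13_P181329 had a fitted interaction of 1.94 ± 0.20 (SE, limma adjusted p = 0.00245), but was not well above background in short days at 25 °C. With that condition at its bound the interaction was at least 1.69 in the scanner software's background-subtracted signal. It was 0.94 in the authors' values and 0.84 after recentring those. The call was lost in 1 of 23 other settings, quantile normalization (adjusted p = 0.0507). A_13_P000501 had a fitted interaction of 1.43 ± 0.20 (SE, limma adjusted p = 0.0177), but was not well above background on any long-day array, so its temperature change in long days was not measured. Its call was kept in 15 of 23 other settings, lost in 7 and of opposite sign without a call in 1.

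For each simple comparison, the 6 arrays can be split in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 3577 calls for temperature in short days (highest other 0), 3955 in long days (highest other 2), 827 for day length at 15 °C (highest other 1) and 1586 at 25 °C (highest other 1). For the averaged effects, 100 splits were used, with the real one included. They were made within the levels of the other factor and without regard to slide. They argue against chance, though 1 of 100 is the smallest share they could give. Only the real split, 1 of the 100, reached 6549 calls for temperature (highest other 194) and 2189 for day length (highest other 29).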

How the results depend on the processing

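The recentred authors' values, and the correlation between the averaged effects in every setting, were chosen after the data were seen, and the other alternatives before. Of the 16 named values of the simple comparisons, 13 kept their direction and call in every setting run, and the others kept their direction. Sizes moved more, with A_13_P000501 at -4.93 to -1.52 on the log2 scale over the settings at 15 °C, A_13_P120660 at 5.19 to 7.89 in short days and 4.27 to 7.29 in long days, A_13_P108750 at 2.52 to 6.55 in long days and A_13_P136610 at 1.24 to 4.11 at 15 °C. Of the named interactions, A_13_P000501, not well above background in long days, was -0.55 with normexp (adjusted p = 0.538, range over settings 0.00391 to 0.538). Counts are given here in the order temperature in short days and in long days, day length at 15 °C and at 25 °C, interaction, averaged temperature and averaged day length, where they moved by over 1.5 times. Against 3577, 3955, 827, 1586, 111, 6549 and 2189, testing all 43603 probes gave 1809, 1830, 433, 761, 20 and, for averaged day length, 1285. Only the arrays compared, which leave fewer degrees of freedom, gave 2027 for temperature in short days and 531 and 517 for day length. Array weights gave 6441 for temperature in long days, 1440 and 2834 for day length, 441 for the interaction and 3388 for averaged day length. Array medians gave 909 for temperature in long days, 288 for day length at 15 °C, 28 for the interaction and 4238 for averaged temperature. Normexp gave 1847 for day length at 15 °C, and quantile normalization 64 for the interaction. Membership moved as well. Of the main calls, normexp called 2117, 2384, 598, 951, 47, 4203 and 1373 again in the same direction, in the order above. The authors' values called 2203, 2791, 578, 1048, 56, 4754 and 1472 of them again in that direction. The authors' values gave 1315 and 6128 for day length and 7365 for its average, and recentred 2384 at 25 °C and 287 for the interaction. For the interaction a fixed slide block gave 53 and a block on the replicate number 38. That replicate block moved no other count by over 1.5 times, and the numbers are not known to pair the samples, since same-numbered arrays correlated at -0.230 to 0.161 after removing group means and 2 of 12 arrays correlated best with their own number. Slides tied the arrays more, since 7 of 18 same-slide pairs correlated above 0.1, at up to 0.370, and 8 of 12 arrays correlated best with their own slide. The correlation of temperature responses, 0.547, was 0.402 with normexp, 0.354 without a filter and 0.614 over probes well above background on all 12 arrays. That of day length responses, 0.325, was 0.167, 0.224 and 0.404 in these settings and 0.402 in the authors' values, recentred or not. The causes of these moves were not tested. Leaving out each array gave, in the order above, 2166 to 3952, 2239 to 4021, 479 to 918, 805 to 1512, 26 to 100, 5373 to 6461 and 1499 to 2054 calls, correlations of 0.479 to 0.546 for temperature and 0.265 to 0.344 for day length, and -0.267 to -0.160 between the averaged effects. The set tests of gene lists, and their alternatives, were not run because no target identifier matched the reference table used. With the median spot 1.27 to 1.75 times as bright as negative controls, the levels of dim probes are known only as bounds.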

Other observations

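The correlation between the averaged effects was computed only after the data were seen, and the tests that weigh it were fixed before their own results were seen. Warm growth and long days tended to move the same transcripts in opposite directions. Of the probes called for both averaged effects, 537 were higher at 25 °C and lower in long days, where independent lists would share 198, and 434 were lower at 25 °C and higher in long days, where they would share 136. Only 127 were higher and 90 lower under both, fewer than the 149 and 181 of independent lists. The calls for both effects used the same arrays and the same spread per probe, so their lists are not independent. Across the 21576 probes the averaged effects correlated at r = -0.236 (Spearman rho -0.283), and at -0.171, 0.02 and -0.346 within slides 1, 2 and 3, so slide 2 did not show it.

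Shared noise of single arrays was weighed as a cause of this opposition. The temperature effect on each slide was set against the day length effect on the other slides, which share no array, and the correlations were -0.238, -0.199 and -0.128, with a mean of -0.188, which argues against noise as the whole cause. Dim probes are argued against too, since r was -0.270 over the 17103 probes well above background on all 12 arrays. After quantile normalization, with the dim probes kept, r was -0.245, which does not bear on them. In the 5% of probes with the largest temperature rises on a slide, the median day length effect on the other slides lay below that of the 5% with the largest falls by a mean difference of -0.28 on the log2 scale. That difference restates the correlations across slides, and no test here separated an expression state shared by warm-grown and short-day plants from a difference in plant age or time of day at harvest, so these stay open. Array brightness was not tested as a cause either. Before scaling, the 75th percentile of log2 signal was 11.02 to 11.43 in short days at 15 °C and long days at 25 °C. It was 10.48 to 10.92 in the other conditions. This split held on every slide, so the comparison across slides could not exclude it.

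In the authors' deposited values, 92.3% of the calls for day length at 25 °C were rises. There the median change of the tested probes was 0.19 on the log2 scale and that of the 22027 untested ones -0.0067, and after recentring on the tested probes 49.3% of the calls were rises. Recentring sets that median near 0, so the lower share follows largely from it, and whether centring on all spots, many of them at background, made the excess stays open. Which centring is nearer to the RNA content of the plants was not tested.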
